A study of Mus musculus with 4 samples.

How the data were processed

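RNA was measured in ILC2s sorted from the lungs of wildtype and basophil-depleted mice 5 days after hookworm infection, with 2 pooled samples per group. Per the labels' protocols, cells were live, CD45-positive and lineage-negative (lineage markers of T, B, NK, myeloid and red cells and of basophils and mast cells) and CD90- and CD127-positive, with a purity of 98% or more. RNA was amplified linearly before library construction, per the labels' protocols. How basophils were depleted is not given in the sources used here.

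Per the submitters' processing notes, the tools named are bcl2fastq 2.20.0.422, FastQC 0.11.8, Picard 2.21.1, SAMtools 1.9, edgeR 3.26.5, cutadapt 2.5, STAR, featureCounts 1.6.4, StringTie 2.0 and DESeq2 1.22.1, with the genome build GRCm38. The notes give these names without a role or an order, and whether reads were counted by strand is not given in the sources used here. The deposited table holds 46078 genes by Ensembl identifier. The authors deposited per-library values that are a normalised signal, gene counts divided by a size factor. The authors also deposited a log2 fold change of basophil-depleted over wildtype, its standard error, a score (the test statistic), a p-value and an adjusted p-value for each gene, with an adjusted p for 17879 genes. The deposited mean of each gene is a normalised signal and equals the mean of its 4 library values. The adjusted p-values of this table are named as the authors' throughout.

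Within each library every deposited value is a whole multiple of the smallest one, the worth of 1 read (0.788 for wildtype 1, 1.69 for wildtype 3, 0.781 for basophil-depleted 2 and 0.93 for basophil-depleted 3). Divided by it, 100% of values were whole within 1e-06, so the recovered reads came to 44027445 for wildtype 1, 21004909 for wildtype 3, 46687995 for basophil-depleted 2 and 38422955 for basophil-depleted 3. Wildtype 3 had the fewest reads, so a value rests on fewer reads there. Gene identifiers were joined to GENCODE M21 (GRCm38), where 45229 of the 46078 were found. In 160 cells a symbol was repeated and its first copy was used, and 284 empty symbols were filled from a gene name table. Replicates were compared before use: the chi-square per degree of freedom between the wildtype libraries was 156, and 49.5 between the depleted ones, so no library was a copy of another.

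The main test was limma 3.58.1 (R 4.3.3; empirical Bayes with a mean-variance trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05. It ran on the 16272 genes with a value of at least 10 in at least 2 libraries, and 29806 genes were left out. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. With 2 libraries per group the fit has 2 residual degrees of freedom. Because the unit is a normalised one, count tests on the recovered reads were alternatives: edgeR 4.0.16 (quasi-likelihood, TMM or DESeq2 size factors), DESeq2 1.42.0 and limma voom. Other alternatives were pseudocounts of 0.5 and 4, no filter, a mean of at least 50, TMM and quantile scaling of the values, robust empirical Bayes, and leaving out each library. Chosen after seeing the data were DESeq2 without wildtype 3 and DESeq2 with every library thinned to the reads of wildtype 3. The main test, the lists and the other alternatives were fixed before the data were examined.

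Fixed gene lists numbered 38 (23 of biology or RNA quality and 15 of cell type markers), each tested by camera with a preset correlation of 0.01 against all other tested genes, with at least 5 tested members. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. That version of camera judges a list on the 2 residual degrees of freedom, so it had little power here. A call lost there decides little on its own. Counts of members are given over all genes tested and adjusted over the list alone. Some lists share genes, so their results are not independent. For example, Hdc is in the basophil and mast cell lists and Ear2 in the eosinophil and macrophage lists. Il1r2 is in the neutrophil and the alarmin and cytokine receptor lists, and ILC2s hold it at a high level.

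Named genes followed a fixed rule. Genes past the threshold with both depleted libraries on the same side of both wildtype libraries, a mean of at least 50 in the higher group and a symbol that is not a predicted-gene name were to be ranked by fold, 12 in each direction. Since fewer than 5 passed, the 12 with the smallest p in each direction under the same conditions without the threshold were named, as not having passed. The rule further took up to 4 called members of each biology list (limma called none), the 2 members with the highest mean of each list called by camera, and Nmbr, Grpr, Nmur1, Gata3, Il1rl1, Il5, Il13, Il4, Areg, Arg1 and the highest marker of each cell type list. Genes named as called in the authors' deposited table, Cacnb3, the processed pseudogenes and the families of the closing section were chosen after their values were seen.

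The tests were tested on simulated data for the comparison of basophil-depleted with wildtype libraries, with 200 of 16272 genes changed. At a low dispersion limma called 82% of genes changed 2-fold, 92% of those changed 4-fold, 94% of those changed 8-fold and 100% of those changed 16-fold, with 19 false calls among 203. DESeq2 called 80%, 80%, 90% and 96% at the same folds. A first run had required every tool to call more than 80% of genes changed 4-fold at low dispersion, and DESeq2, at 80%, did not meet this. The requirement was then limited to genes with a mean of at least 30, a split chosen after that run. Of those genes DESeq2 called 40 of 41 changed 2-fold, 36 of 36 changed 4-fold, 40 of 41 changed 8-fold and 41 of 41 changed 16-fold. At the dispersion estimated from these libraries limma called 12%, 50%, 72% and 80% at those folds with 3 false calls, and DESeq2 16%, 56%, 72% and 84% with 24 false calls among 138. In 10 simulations without any change limma called 0 to 1 genes, edgeR 0 and DESeq2 0 to 14. Genes were drawn independently of each other, so shifts of many genes together within a pool were not simulated. These counts therefore set no upper bound on false calls in the real libraries. Closest parent transcripts of pseudogenes were found with BLAST+ 2.17.0.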

Results

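The data were RNA-seq profiles of group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines, sorted from mouse lung 5 days after infection with the hookworm Nippostrongylus brasiliensis. The comparison was between wildtype mice and mice depleted of basophils, and the series title places it in the question of how basophils affect the inhibition of ILC2s by neuropeptides. Cells of 6 biological replicates per group were pooled into 2 samples per group, which gave 4 libraries: wildtype 1 and 3, and basophil-depleted 2 and 3. Each library is a pool, so the spread between libraries is a spread between pools. Whole reads recovered from the deposited values came to 44027445 for wildtype 1, 21004909 for wildtype 3, 46687995 for basophil-depleted 2 and 38422955 for basophil-depleted 3. All values below are normalised read counts (reads divided by the library's size factor), given as the mean ± SD of n = 2 libraries unless a single library is named, and gene positions are those of GENCODE M21 on GRCm38.

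In the authors' deposited table, genes lower in ILC2 samples of basophil-depleted mice included the chemokine Ccl22, the granzymes Gzma and Gzmc and the lysozyme Lyz2, and genes higher in them included the decoy receptor Il1r2 and the chemokine receptor Ccr10. No gene passed the limma test used here. Camera called 11 of 15 lists of cell type markers lower too, a result that was lost with an estimated correlation (smallest adjusted p = 0.404). With 2 residual degrees of freedom that version had little power. Ccl22, a chemokine that binds CCR4 (chromosome 8, 94745590 to 94751699), stood at 1434 ± 99.3 in wildtype and 112 ± 19.8 in basophil-depleted libraries. Fscn1, an actin-bundling protein, stood at 995 ± 38.2 and 109 ± 4.56, and the granzyme Gzmc at 3971 ± 2509 and 161 ± 75.0. The authors' deposited table gave 245 genes an adjusted p under 0.05, of which 224 were lower and 21 higher in basophil-depleted mice. In the limma test on the log2 values, none of 16272 genes had an adjusted p under 0.05, while 900 had an unadjusted p under 0.05. With no difference at all, a share of 0.05 of the tested genes would be expected under that bound, which is near this count. The quasi-likelihood test of edgeR and limma voom on the recovered reads also called 0 genes, with 1005 and 762 at an unadjusted p under 0.05, and DESeq2 called 248 (26 higher and 222 lower). Without wildtype 3, which stood apart from the other libraries, limma called 29 genes (20 higher, 9 lower) and DESeq2 286 (183 higher, 103 lower). Without wildtype 1, limma called 125 genes (7 higher, 118 lower), and without basophil-depleted 2 it called 1.

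**Figure D1:**
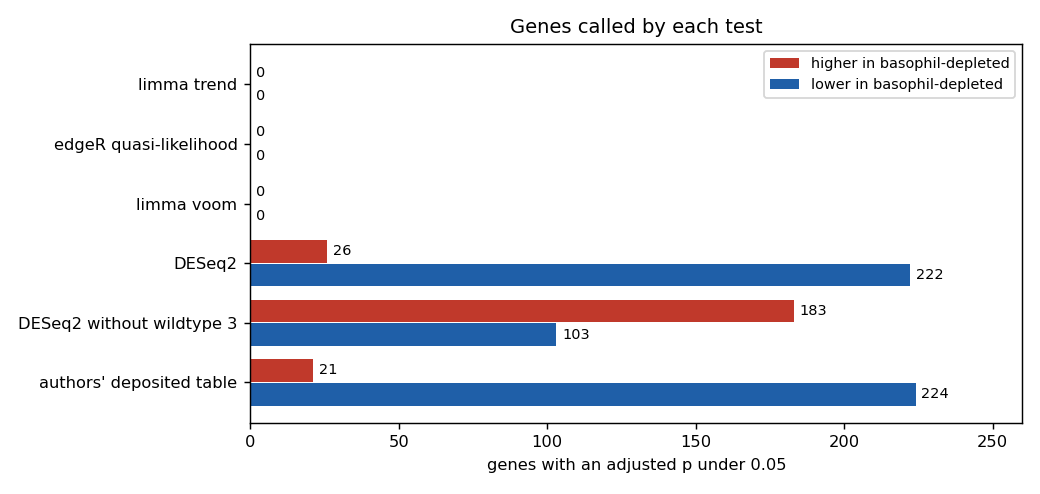
Number of genes with an adjusted p under 0.05 (horizontal axis) in each test (vertical axis), with bars in red for genes higher and in blue for genes lower in basophil-depleted mice. The limma and edgeR tests called 0 genes, DESeq2 called 26 higher and 222 lower, and the authors' deposited table holds 21 higher and 224 lower.

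Among genes that met the conditions of the naming rule, 12 with the smallest p in the lower direction were named. They were Ccl22, Gzmc, Fscn1, Emilin2, Gzma, Igkv17-121, Chil3, Cd3e, Serpinb6b, Ccl5, Cd8b1 and Nkg7, and none passed the limma threshold. For Ccl22 the limma log2 fold change was -3.67 (SE 0.37, adjusted p = 0.111), which was also the smallest adjusted p of the test. Gzmc had a limma log2 fold change of -4.54 (SE 0.52, adjusted p = 0.111), and Gzma, a second granzyme, one of -2.84 (SE 0.36, adjusted p = 0.111). Gzma stood at 8265 ± 2269 in wildtype and 1191 ± 530 in basophil-depleted libraries. The chemokine Ccl5 stood at 14927 ± 19.9 and 5760 ± 1159, and Nkg7, a protein of cytotoxic granules, at 6487 ± 1169 and 2056 ± 586. Cd3e, a chain of the T cell receptor complex, stood at 2549 ± 380 and 599.7 ± 240, and Cd8b1 at 596 ± 270 and 66.5 ± 25.6. Chil3, a chitinase-like protein, reached 5617 in wildtype 1 and 14354 in wildtype 3, against 1170 and 1263 in the depleted libraries. The immunoglobulin segment Igkv17-121 was at 148 in wildtype 1 and 163 in wildtype 3 and was without a read in both depleted libraries. The authors' deposited table lists each of these 12 genes as lower, with adjusted p-values that include 8.9e-20 for Ccl22 and Gzmc, 1.9e-13 for Fscn1 and 0.00106 for Ccl5.

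Under the same conditions, the 12 genes with the smallest p in the higher direction were named. They were Gt(ROSA)26Sor, Msc, Il1r2, Ccr10, Tmem250-ps, Tnfrsf8, Ipo7, Eml2, Tubal3, Rbbp4, Lgals3 and Sdc4, and none passed the limma threshold. Il1r2, which binds interleukin-1 without signalling (chromosome 1, 40074079 to 40125231), stood at 9478 ± 213 in wildtype and 20114 ± 2571 in basophil-depleted libraries, a limma log2 fold change of 1.08 (SE 0.22, adjusted p = 0.559). Ccr10, the receptor of the chemokines CCL27 and CCL28, stood at 292 ± 82.5 and 1103 ± 401. The transcription factor Msc stood at 193 ± 11.5 and 680.0 ± 5.07, and Tnfrsf8 (CD30) at 273 ± 45.5 and 912 ± 349. Gt(ROSA)26Sor, the transcript of the ROSA26 locus (chromosome 6, 113067428 to 113077333), was at 8.67 and 30.5 in the wildtype libraries and at 208 and 350 in the depleted ones. Tubal3 was at 2.36 in wildtype 1 and without a read in wildtype 3, against 24.2 in basophil-depleted 2 and 355 in basophil-depleted 3. The authors' deposited table lists Gt(ROSA)26Sor, Msc, Il1r2, Ccr10, Tmem250-ps, Tnfrsf8, Ipo7, Eml2 and Tubal3 as higher, and gives Rbbp4, Lgals3 and Sdc4 adjusted p-values of 0.075, 0.0658 and 0.107.

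**Figure D2:**
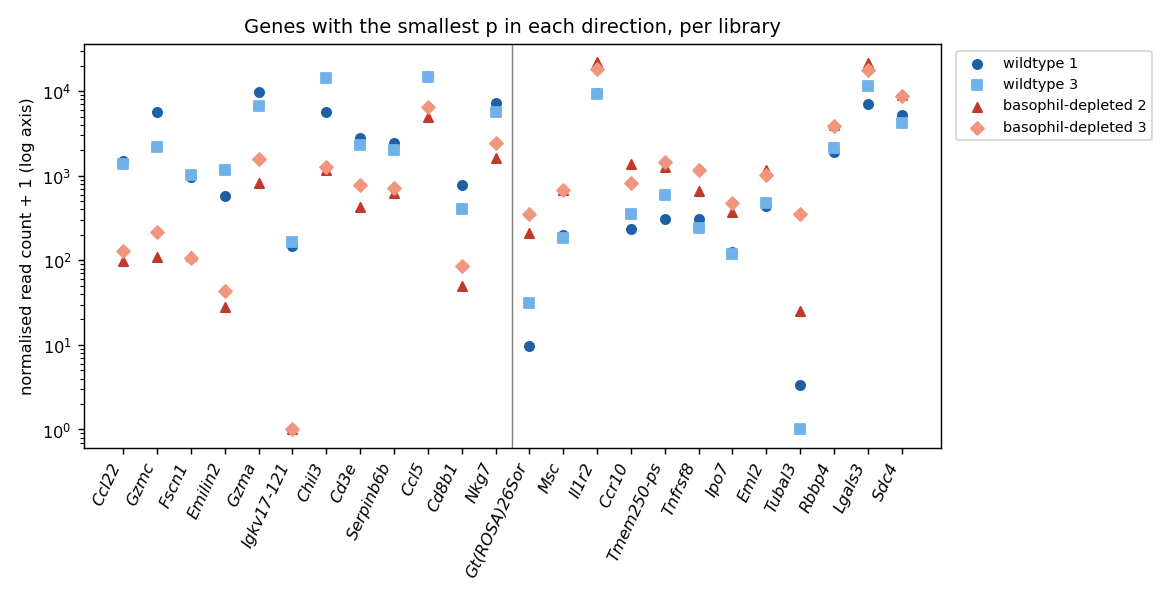
Normalised read count plus 1 on a log axis (vertical) for 24 genes (horizontal axis, lower genes left of the line), with 1 point per library and a colour and shape for each library. These genes had the smallest limma p in each direction among those that met the conditions of the naming rule. Both depleted libraries lie on the same side of both wildtype libraries for every gene, which the rule for choosing them required, and Ccl22 is at 1504 and 1364 in the wildtype libraries and at 98.4 and 126 in the depleted ones.

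The receptors that bear on the series title were measured at very different levels. Nmbr, the receptor of neuromedin B (chromosome 10, 14705591 to 14770850), had 0 reads in wildtype 1, 27 in wildtype 3, 3 in basophil-depleted 2 and 3 in basophil-depleted 3, and was too low for the main test. Without the filter on low values its limma log2 fold change was -0.94 (SE 1.78, adjusted p = 0.876), smaller than the SD of 3.92 between the wildtype libraries on that scale. It was -3.71 without wildtype 1 and 1.83 without wildtype 3, so the sign for Nmbr rests on single libraries. Grpr, the receptor of gastrin-releasing peptide, had between 0 and 6 reads per library and was likewise too low for the main test. Nmur1, the neuromedin U receptor that activates ILC2s, stood at 1223 ± 3.07 in wildtype and 1558 ± 52.0 in basophil-depleted libraries (limma adjusted p = 0.955). Of 16 tested receptors for neuropeptides and neurotransmitters, 0 were called by limma over all genes and 0 when adjusted over the list alone. The authors' deposited table has 2 of them lower, the serotonin receptor Htr7 (adjusted p = 0.0171) and Vipr1, a receptor of vasoactive intestinal peptide (adjusted p = 0.0336). Vipr1 differed between the wildtype libraries, with 124 in wildtype 1 and 525 in wildtype 3. The list had a camera adjusted p of 0.0618 (0.404 with an estimated correlation).

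Limma called no difference among the genes that define ILC2s. Gata3, the transcription factor that ILC2s need, stood at 45391 ± 732 in wildtype and 60107 ± 6925 in basophil-depleted libraries (limma adjusted p = 0.92). Il1rl1, the interleukin-33 receptor, stood at 19288 ± 5772 and 21158 ± 2094, a log2 fold change of 0.16 that changed sign without wildtype 3. Among 29 tested members of the ILC2 identity list, 17 had a positive and 12 a negative log2 fold change, 0 were called by limma over all genes or adjusted over the list alone, and the camera adjusted p was 0.3. Without wildtype 3, DESeq2 called 1 member higher, the TSLP receptor chain Crlf2 (adjusted p = 0.0228), which was named after its value was seen and was at 3110 in wildtype 1, 5562 in wildtype 3, 6801 in basophil-depleted 2 and 5210 in basophil-depleted 3. With all 4 libraries the adjusted p of Crlf2 was 0.931 in limma, 0.962 in edgeR and 0.982 in DESeq2. The type 2 cytokines Il13 (19206 ± 2805 and 28352 ± 3673), Il5 (7924 ± 718 and 7609 ± 918) and Il4 (1689 ± 72.0 and 1110 ± 107) had limma adjusted p-values of 0.898, 0.991 and 0.91. Arg1, an arginase that ILC2s hold at high levels, stood at 50768 ± 6410 and 79489 ± 14204, and the growth factor Areg at 21224 ± 2458 and 15013 ± 3526, with limma adjusted p-values of 0.89 and 0.91.

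Among the lists of signalling genes, camera called the type 2 cytokine and effector list lower as a set (31 tested members, median log2 fold change -0.46, adjusted p = 0.000342, and 0.404 with an estimated correlation, which ended the call). The median was -0.29 without wildtype 1 and -0.27 without basophil-depleted 2. The 6 tested members with the most negative log2 fold changes were the chemokines Ccl22 (-3.67), Ccl3 (-3.10), Ccl17 (-2.82) and Ccl4 (-2.79), the cytokine Il3 (-1.94) and the chemokine Ccl5 (-1.39). Limma called 0 of its members over all genes and 5 adjusted over the list alone, all lower. The authors' deposited table lists Ccl3, Ccl4, Ccl5 and Ccl22 as lower and no member as higher. Ccl5 is also a marker of NK cells and Ccl17 of dendritic cells, and camera called both marker lists lower (each with an adjusted p of 0.404 with an estimated correlation). Camera also called the alarmin and cytokine receptor list lower (38 members, median -0.096, adjusted p = 0.0218), with 2 lower and 1 higher member adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.404). It was also lost without a filter, without wildtype 1, without wildtype 3 and without basophil-depleted 3 (adjusted p = 0.0709, 0.0519, 0.129 and 0.0521, within a range of 0.0031 to 0.139 over all alternatives). Its median was -0.16 without wildtype 1 and -0.15 both without basophil-depleted 3 and with quantile scaling. Il2rg, its member with the highest mean, stood at 32387 ± 3042 and 30994 ± 3500 and was not called. The authors' deposited table lists Csf2rb, Csf2rb2 and Tnfrsf9 as lower and Il1r2 as higher in that list. The checkpoint and costimulatory list was lower by camera (30 members, median -0.26, adjusted p = 0.00348), as were interferon response genes (40 members, median -0.25, adjusted p = 0.000646) and MHC class II genes (13 members, median -0.64, adjusted p = 5.15e-07), each with an adjusted p of 0.404 with an estimated correlation. Limma adjusted over the list alone called 1, 0 and 2 of their members lower. The checkpoint call was lost without wildtype 1 (adjusted p = 0.2, range 0.000543 to 0.2) and the interferon call without basophil-depleted 2 (adjusted p = 0.108, range 7.9e-05 to 0.108). The checkpoint median was -0.15 without wildtype 1, and the interferon median -0.40 without basophil-depleted 3. Among the members with the highest means, Cd44 stood at 26705 ± 5122 and 41210 ± 2278, Icos at 31465 ± 2121 and 26416 ± 5380, Psmb8 at 23116 ± 961 and 23424 ± 985, and Tap1 at 7653 ± 1034 and 9185 ± 595. Beside these lists camera called macrophage, dendritic cell and B cell markers lower, cells that hold MHC class II (each with an adjusted p of 0.404 with an estimated correlation). The MHC class II median was -1.06 without wildtype 1 and -1.03 without basophil-depleted 3. Cd74, the invariant chain of MHC class II, stood at 29999 ± 8923 and 13581 ± 2190. Oxidative phosphorylation genes were lower by camera (44 members, median -0.20, adjusted p = 0.00728, 0.849 with an estimated correlation) and proliferation genes higher (36 members, median 0.24, adjusted p = 0.00736, 0.849 with an estimated correlation). Limma called 0 members of either list adjusted over the list alone. Without wildtype 3, which stood apart, both directions turned, with adjusted p-values of 0.683 (range 4.99e-06 to 0.683) and 0.849 (range 1.35e-11 to 0.849). The oxidative phosphorylation call was also lost without basophil-depleted 2 (adjusted p = 0.176) and without a filter (adjusted p = 0.0506), and its median was -0.45 without wildtype 1. Proliferation also turned without basophil-depleted 3 (median -0.11, adjusted p = 0.232) and lost its call with quantile scaling (adjusted p = 0.075), and its median was 0.51 without wildtype 1 and 0.58 without basophil-depleted 2. Atp5b, of oxidative phosphorylation, stood at 47522 ± 5580 and 57114 ± 351, and Top2a, of proliferating cells, at 9185 ± 1770 and 11464 ± 3827. The other biology and RNA quality lists were not called in this test. Under single alternatives camera called ribosomal proteins lower with a mean of at least 50, without wildtype 1 and without basophil-depleted 2 (adjusted p = 0.0153, 7.1e-05 and 0.048, against 0.125 in the main test). It likewise called mitochondrially encoded genes lower without wildtype 3 (adjusted p = 0.017), and without basophil-depleted 2 heat shock genes higher (adjusted p = 0.00894) and neuropeptide and neurotransmitter receptors lower (adjusted p = 0.0497). Among the lists not called, the median and mean differed in sign for lipid mediator receptors (0.15 and -0.12), STAT5 and STAT6 response (0.12 and -0.033), TGF-beta response (0.035 and -0.028), immediate early genes (-0.047 and 0.041) and glycolysis (0.015 and -0.058).

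Markers of cell types other than ILC2s differed between the groups, although the sort gate excluded most of these cells. Camera called 11 of 15 cell type lists lower in basophil-depleted mice, and all 11 calls were lost with an estimated correlation (smallest adjusted p = 0.404). For T cell markers that correlation was -0.015, below the preset 0.01, and the unadjusted camera p still rose from 1.2e-12 to 0.017. For NK cell and ILC1 markers the correlation was high (0.937). With 2 residual degrees of freedom that version had little power, so the loss decides little on its own. Of 16 tested markers of NK cells and ILC1s, 16 had a negative log2 fold change, and 13 were lower in limma adjusted over the list alone (median -1.92, camera adjusted p = 7.9e-21, and 0.404 with an estimated correlation). Without basophil-depleted 2 this median was -1.25. Wildtype 3 lay above wildtype 1 by a median of 2.88 on the log2 scale over B cell markers, 2.13 over macrophage and monocyte markers, 2.5 over neutrophil markers and 5.39 over lung epithelium markers. Lyz2, a lysozyme of myeloid cells, was at 3267 in wildtype 1, 13271 in wildtype 3, 961 in basophil-depleted 2 and 1324 in basophil-depleted 3. The immunoglobulin constant gene Igkc was at 4489 and 30368 in the wildtype libraries and at 1633 and 904 in the depleted ones. The median log2 fold change was -2.84 over 13 B cell markers, -2.45 over 17 macrophage and monocyte markers, -2.56 over 9 neutrophil markers, -2.58 over 11 dendritic cell markers and -3.01 over 6 eosinophil markers. Without wildtype 3 these medians were -1.10, -0.89, -1.63, -1.48 and -1.60 in that order, and without wildtype 1 they were -4.58 for B cell and neutrophil markers. The dendritic cell median was -1.53 without basophil-depleted 2. Of the 11 dendritic cell markers 9 had a negative and 2 a positive log2 fold change. Xcr1, a positive one, stood at 682 ± 66.1 in wildtype and 1080 ± 93.4 in basophil-depleted libraries. T cell markers had a median of -1.26 over 14 genes, fibroblast and smooth muscle markers -1.73 over 14, lung epithelium markers -1.01 over 16 and mast cell markers -1.94 over 5. Without wildtype 3 the T cell and fibroblast medians were -0.82 and -0.40. The fibroblast median was -2.76 without wildtype 1 and -0.80 without basophil-depleted 3, and the lung epithelium median was -3.18 without wildtype 1, -2.25 with DESeq2 and with edgeR and TMM, and -0.62 with voom, where its call was lost (adjusted p = 0.0786). The eosinophil median was -1.40 without a filter. Basophil markers had a median of -1.03 over 11 genes (camera adjusted p = 5.03e-05, and 0.404 with an estimated correlation). This median was -0.75 without wildtype 3, -2.57 without wildtype 1 and -2.11 with DESeq2, and Mcpt8, a basophil protease, was at 34.7 and 120 in wildtype and at 1.56 and 0 in depleted libraries. Gamma delta T cell, ILC3, endothelium and erythroid and platelet lists were not called (camera adjusted p = 0.125, 0.743, 0.676 and 0.0515). The endothelium list was called lower without wildtype 1 (adjusted p = 0.00018) and higher without wildtype 3 (adjusted p = 0.00172). The gamma delta T cell list was called lower without wildtype 3 (adjusted p = 0.0309), and the erythroid and platelet list with a mean of at least 50, without wildtype 1 and without basophil-depleted 2 (adjusted p = 0.000525, 0.0498 and 3.0e-08). Fry called none of the 38 lists. Without wildtype 3 the lung epithelium list turned to higher (median 1.34, camera adjusted p = 0.0289, range 2.85e-10 to 0.0786). The eosinophil and fibroblast lists were then no longer called (adjusted p = 0.051 and 0.127). The called lists did not fall evenly. Their highest marker was Osbpl8 for basophils (log2 fold change -0.16), Kit for mast cells (-0.10), Trbc2 for T cells (-0.18) and Ctsd for macrophages (-0.33). It was Bst2 for dendritic cells (0.016), Thy1 for fibroblasts (-0.057) and Il1r2 for neutrophils (1.08). For NK cells it was Ccl5 (-1.39), for B cells Igkc (-3.26), for eosinophils Ear2 (-2.70) and for lung epithelium Scgb1a1 (-1.78). Some markers are abundant in every library, such as Kit, Cpa3, Thy1 and Il1r2, so a list's members need not all come from its cell type.

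**Figure D3:**
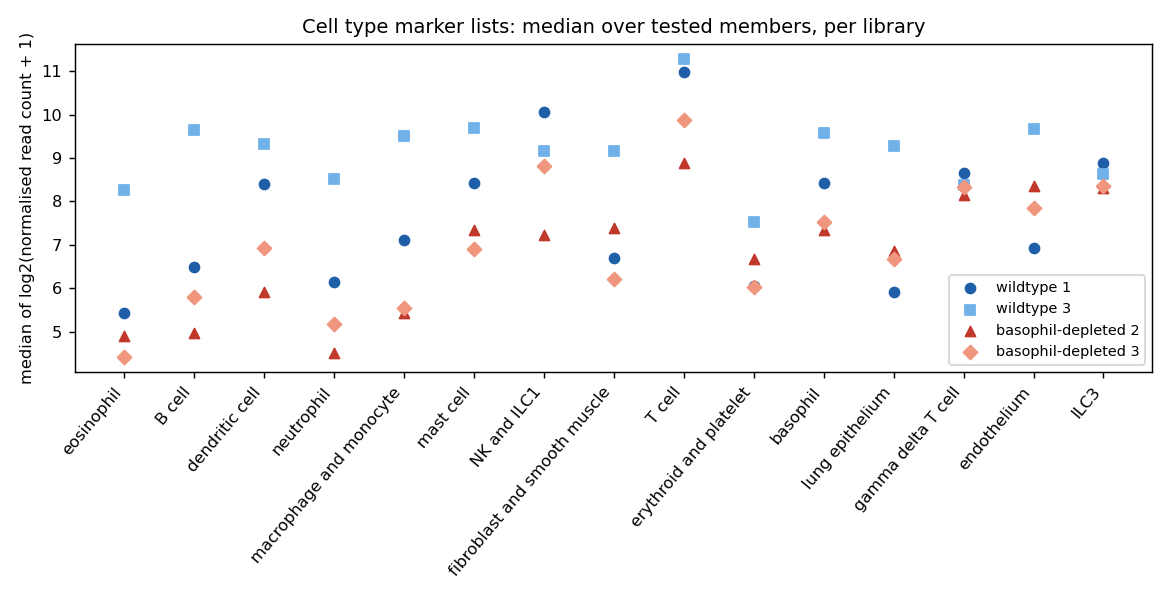
Median of log2(normalised read count + 1) over the tested members (vertical axis) of each of 15 cell type marker lists (horizontal axis), with 1 point per library. Wildtype 3 lies above the other libraries for most lists, with a median of 9.65 for B cell markers against 6.49 in wildtype 1, 4.98 in basophil-depleted 2 and 5.8 in basophil-depleted 3.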

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

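No paired analysis was possible because the groups share only 1 replicate number (3). Leaving out 1 library leaves 1 group with a single library, which is assumed to vary like the other group. The limma count of 0 changed genes stayed at 0 with pseudocounts of 0.5 and 4, edgeR with either scaling, voom, TMM on the values, quantile scaling and robust empirical Bayes. It was 7 without a filter (1 higher, 6 lower), 5 with a mean of at least 50 (0 higher, 5 lower) and 248 with DESeq2 (26 higher, 222 lower). The added DESeq2 alternatives, chosen after seeing the data, gave 286 with wildtype 3 left out (183 higher, 103 lower) and 205 on thinned reads (17 higher, 188 lower). Leaving out each library gave 0 to 125 changed, 0 to 20 higher and 0 to 118 lower genes, with the highest total without wildtype 1. Camera called 18 lists and between 16 and 20 under every alternative fit. Of the 18, 12 were still called without wildtype 3, 13 with DESeq2 and wildtype 3 left out, and 16 or more in each other fit, in the same direction. With an estimated correlation 0 were called, and with fry 0. The Nmbr log2 difference was -0.94 and ran from -3.71 without wildtype 1 to 1.83 without wildtype 3, within its wildtype SD of 3.92. None of the 67 named genes lost a call, as none had one, and DESeq2 called 28 of them. Wildtype 3 had the fewest reads, so low values there rest on fewer reads. That library still had the most genes with a read, at 24829. The others had 23662 (wildtype 1), 24144 (basophil-depleted 2) and 23608 (basophil-depleted 3). For the differences between tests the cause was not tested. For lists, the camera direction changed and the value is the median log2 fold change. Without a filter the values were 0.18 for the lipid mediator receptors list, -0.047 for the immediate early and dissociation response list and -0.020 for the apoptosis and survival list. With a mean of at least 50 the values were 0.015 for the glycolysis list. With edgeR and TMM the values were -0.014 for Psmb8, -0.081 for Bst2 and -0.020 for the glycolysis list. With edgeR and DESeq2 size factors the values were -0.011 for Psmb8, -0.075 for Bst2 and -0.017 for the glycolysis list. With DESeq2 the values were -0.011 for Psmb8, -0.075 for Bst2 and -0.017 for the glycolysis list. With voom the values were -0.0083 for Psmb8, -0.0079 for Cpa3, -0.14 for the ILC3 list and 0.26 for the endothelium list. With TMM on the deposited values the values were -0.014 for Psmb8, -0.018 for Bst2 and -0.019 for the glycolysis list. With quantile scaling the values were -0.034 for Psmb8, -0.032 for Bst2, 0.12 for the STAT5 STAT6 response list, -0.028 for the AP1 NFkB transcription factors list, -0.011 for the glycolysis list, 0.066 for the unfolded protein response list and -0.0019 for the cAMP and G protein signalling list. With DESeq2 and wildtype 3 left out the values were 0.12 for the immediate early and dissociation response list, -0.042 for the proliferation list, 0.037 for the oxidative phosphorylation list, -0.042 for the unfolded protein response list, 0.087 for the ribosomal proteins list, -0.52 for the ILC3 list, 1.52 for the lung epithelium list and 1.00 for the endothelium list. Leaving out each library in turn gave values from -0.18 to 0.051 for Il2rg, -0.024 to 0.062 for Psmb8, -0.75 to 0.44 for Osbpl8, -0.73 to 0.52 for Kit, -0.46 to 0.13 for Trbc1, -0.38 to 0.41 for Bst2, 0.0097 to 0.13 for the STAT5 STAT6 response list and -0.021 to 0.14 for the AP1 NFkB transcription factors list. The same ranges were -0.027 to 0.022 for the glycolysis list, -0.032 to 0.23 for the TGFb response list, -0.35 to 0.17 for the mitochondrially encoded list, -0.15 to 0.47 for Il1rl1, -0.091 to 0.33 for Mcm6, -0.44 to 0.010 for Cox4i1, -1.22 to 0.030 for H2-Ab1 and -0.32 to 0.50 for Cpa3. The same ranges were -4.84 to 1.28 for Scgb1a1, -4.04 to 1.42 for Sftpc, -0.19 to 0.071 for Thy1, -0.18 to 0.063 for Il5, -0.26 to 0.76 for Tcrg-C4, -0.19 to 0.10 for the immediate early and dissociation response list, -0.11 to 0.58 for the proliferation list and -0.45 to 0.026 for the oxidative phosphorylation list. The same ranges were -0.052 to 0.14 for the unfolded protein response list, -0.26 to 0.075 for the ribosomal proteins list, -0.56 to 0.44 for the ILC3 list, -3.18 to 1.34 for the lung epithelium list, -1.44 to 0.97 for the endothelium list, -0.059 to 0.13 for the cAMP and G protein signalling list, -0.055 to 0.64 for Top2a and -0.018 to 0.27 for the heat shock list. The same ranges were -0.025 to 0.26 for the cholesterol and lipid synthesis list and -2.07 to -0.072 for the erythroid and platelet list.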

Other observations

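Gene families chosen after their values were seen, of which some members are also in the fixed lists, differed in which libraries were high. Of 218 immunoglobulin V segments, 97 had a value of at least 10 in wildtype 3, against 19 in wildtype 1, 10 in basophil-depleted 2 and 14 in basophil-depleted 3, and the authors' deposited table lists 14 of them as lower and 0 as higher. A value of 10 takes fewer reads in wildtype 3, where 1 read is worth 1.69, than in the other libraries (0.781 to 0.93). Summed, these segments came to 10413 in wildtype 3, 1392 in wildtype 1, 787 in basophil-depleted 2 and 998 in basophil-depleted 3. The summed values of granzymes were higher in both wildtype libraries, at 18003 in wildtype 1 and 10529 in wildtype 3 against 1425 and 2523 in the depleted libraries. Gzma and Gzmc, already named as lower, made up most of the wildtype sums (9869 and 5745 in wildtype 1, 6661 and 2197 in wildtype 3). Of the 5 granzymes with an adjusted p in the authors' deposited table, 3 are lower and 0 higher. Of the 22 Klr receptors with an adjusted p in the authors' deposited table, 6 are lower and 0 higher. Their 20 members tested here had a median log2 fold change of -2.29. The summed values of the Klr receptors, which a few abundant members can set, did not part the groups, with 31745 in wildtype 1, 18979 in wildtype 3, 23588 in basophil-depleted 2 and 20438 in basophil-depleted 3. Collagens summed to 3640 in wildtype 1, 12499 in wildtype 3, 3842 in basophil-depleted 2 and 2433 in basophil-depleted 3. The tests of other cell types, of a change within ILC2s and of a genotype shared by the depleted mice were chosen only after the result was seen. The comparison of Thumpd3 with the locus it overlaps was also chosen only after the result was seen, while the bound of 0.5 on its own value was set before.

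Of the 224 genes that the authors' deposited table lists as lower, 152 (67.9%) were at least 2 times as high in wildtype 3 as in wildtype 1, against 18.4% of all tested genes. Another 14 of the 224 were at least 2 times as high in wildtype 1 as in wildtype 3. Of the 224, 46 are markers in a cell type list. With every library thinned to the reads of wildtype 3, DESeq2 still called 84.7% as many lower genes (188 against 222, with 173 in both). This argues against unequal depth between libraries as the source of most lower calls of DESeq2. Wildtype 3 itself kept all its reads, so an effect of its own shallow sampling was not tested. Cells of other types in the wildtype pools remain a candidate explanation. Of 55 tested markers of macrophages, neutrophils, B cells and NK cells, 98.2% had a negative log2 fold change, although the sort was gated against these cells at a purity of 98% or more. These lists were taken after their values were seen, so the share describes the pattern and does not test the explanation. ILC3 markers had 5 positive and 5 negative log2 fold changes, and endothelium markers 3 positive and 8 negative ones. Lyz2 was at 3267 and 13271 in the wildtype libraries and at 961 and 1324 in the depleted ones. For Ccl22, Fscn1 and Cacnb3, which were nearly equal in both wildtype libraries, mature dendritic cells may be a source, although the gate excluded CD11c-positive and CD11b-positive cells. Of 8 other genes of such cells, 6 were tested. Their median log2 fold change was -1.14, from -2.34 for Nudt17 to -0.011 for Tmem123, with -0.82 for Ccr7 and -0.34 for Cd83. None was called by limma (smallest adjusted p = 0.672, for Nudt17). None is listed as lower in the authors' deposited table (smallest adjusted p = 0.0588, for Il4i1). The most abundant, Tmem123, was at 9872 and 4930 in the wildtype libraries and at 6901 and 6946 in the depleted ones. A change within ILC2s stays open and cannot be told apart from cells of other types in bulk RNA. The lower genes hold 0 members of the ILC2 identity list, which decides nothing. Only 224 of the 17879 genes with an adjusted p are lower, and the list has 30 genes.

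Of the genes that the authors' deposited table lists as higher, 9 are processed pseudogenes, such as Gm13841, a copy of Rpl29 on chromosome 5 with 1 read in wildtype 1, 0 in wildtype 3, 295 in basophil-depleted 2 and 278 in basophil-depleted 3. A higher level of the parent genes is argued against, since the 8 parents had a median log2 fold change of 0.028. A genotype shared by all depleted mice is argued against for 5 of the pseudogenes, which were at least 10 times higher in 1 depleted pool than in the other, as Gm2451 was at 5.47 and 288. For the 4 pseudogenes that were high in both depleted pools, a sequence variant of the depleted mice and a change in transcription cannot be told apart without the reads, and counts of such copies are uncertain because parent reads match them closely.

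Gt(ROSA)26Sor is a locus where transgenes are often inserted, and it was higher in both depleted libraries. A chromosome 6 haplotype that moved most genes around the locus is argued against. The median size of the log2 fold change of 72 genes within 5 Mb was 0.917 times that of the chromosome. A haplotype that altered only a few genes would hardly move this median, so the test cannot decide on it. A fixed share of the reads of Thumpd3, which overlaps it on the other strand, is argued against, since its log2 fold change of 0.48 (SE 0.29) lay below the 3.95 (SE 0.76) of the locus by 3.48 (SE 0.81). An altered allele at the locus may also account for the pattern and cannot be told apart from other causes here. Of 20 other tested genes within 500 kb, 20% had a log2 fold change over 1 in size, a share between the bounds set before. They were Cidec (-2.02), Il17rc (-1.06), Creld1 (1.02) and Fancd2 (1.08). For Cidec, Il17rc and Fancd2 wildtype 1 and wildtype 3 differed strongly (10.2 and 49.1, 42.5 and 174, 211 and 40.7). Setd5, beside the locus, had a log2 fold change of 0.67 (SE 0.27). The depletion method is not given in the sources used here, so whether it involved this locus was not tested.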
